A study of Homo sapiens with 28 samples.

How the data were processed

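The series holds 28 Affymetrix HG-U133 Plus 2.0 arrays of total RNA from 4 myeloma cell lines, each with 1 array per treatment and 2 untreated arrays. Line, treatment, time and dose of each array come from the labels, where 8226S is written with a slash before the S. The labels also give column purification of total RNA with RNeasy and biotin-labelled complementary RNA as the target. The intensity values in the deposited table were produced by the authors with the GCOS software, per the labels, and its version is not given in the sources used here. In the values themselves each array has a trimmed mean near 500, the mark of scaling to a common target, and no further scaling between arrays was applied here. The 2 array sets were found in the values and are not part of the labels.

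Values were transformed as the log2 of the value plus 29, an offset that damps differences among dim probe sets. Of 54675 probe sets, 41097 carry a single gene symbol in the platform table, 1801 carry several and 11777 were left unnamed. The 62 array controls are counted among these, 56 of them unnamed and 6 under ACTB or GAPDH. Symbols were updated through Entrez identifiers to the RefSeq gene table for 41043 probe sets, for names only. A gene is read from its brightest probe set, which gives 19775 genes with 2.29 probe sets per tested gene on average. Genes above the 50th percentile of their array on at least 4 of the 28 arrays were tested, 15437 in all. Probe sets with several symbols or none were tested apart from the genes. Some members of the lists are not reported here, and list sizes in the text count the members tested.

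All tests used limma 3.58.1 in R 4.3.3. The pooled fit has 6 groups (controls and 5 treatments) and a term for cell line, with lmFit and eBayes with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Every p-value in the text comes from these moderated tests or from limma's camera. For the treatment comparisons, p-values of the moderated tests rest on how far changes differ from line to line, pooled over all treatments. Differences in mean level between lines are removed by the line term. In the pooled fit the difference between the control sets adds to the residual spread. Camera compares the genes of a list with the other genes, so its p-values rest on the spread between genes and on the correlation taken between them. The fit within array sets gives each line in each set its own baseline and was added after the sets were seen. Line differences at baseline were tested with an F test on the controls, and line differences in response with an F test on the interaction of line with arsenic. The residual spread of the baseline test is that between the numbered controls of a line, which lie in different array sets. Unless the control number is added, it thus holds the set difference. No line has replicate untreated arrays within a set. Within a line, a treatment has 1 array, so the number of arrays limits the precision of every value.

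The cell lines pair the arrays across treatments. This was checked in the values, where deviations of an array from the mean of its group correlated with those of the same line at 0.737 on average (lowest 0.600) and with those of other lines at -0.0519 at most. Subtracting the group mean pushes the values between lines below 0 by construction, so only the values of the same line bear on the pairing. No column was a copy of another, with a highest correlation of 0.972 between arrays. The first 3 principal components held 26.3%, 20.8% and 18.1% of the variance, and the second of them separated the 2 sets, from 12.8 to 82.8 in set 1 and from -56.7 to -9.75 in set 2.

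The 22 gene lists were written before the data were examined: metallothionein and metal, NRF2 targets, heat shock, ATF4 stress response, proteasome, ubiquitin and autophagy, arsenic and glutathione handling, ER chaperones, cholesterol synthesis, plasma cell identity, G1/S, G2/M, MYC and ribosome biogenesis, glycolysis and hypoxia, immediate early AP-1, NF-kB, interferon, p53, the 2 sides of the BCL2 family, markers of other cell types, and translocation markers. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, with fry, and within sets. Genes named in the text are the largest changes with the same sign in the 4 lines, the list members with the smallest p, or a short set chosen in advance that includes HMOX1, MT2A, GCLM, DDIT3, PMAIP1, BMF, MCL1 and CDKN1A.

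In a test on simulated values, 200 of 15437 genes were changed and the shift between sets was simulated as well. Within sets 89.4% to 95.5% of genes changed by 2 log2 units were called, 56.7% to 65.7% of those changed by 1 and 7.46% to 22.4% of those changed by 0.5. The pooled fit called 84.8% to 92.4%, 41.8% to 61.2% and 2.99% to 25.4%. Of its calls 15 of 118, 30 of 141 and 21 of 129 were unchanged genes for ATO at 6, 24 and 48 h, and 15 of 121 and 11 of 109 for DAR at 6 and 24 h, above the nominal 5% in each. Within sets unchanged genes were 9 of 121, 9 of 125 and 6 of 112 calls for ATO, above 5% as well, and 4 of 112 and 5 of 119 for DAR. Each comparison was simulated once, so counts this small do not tell whether the rate within sets lies above 5%. A response of 2 log2 units in a single line was called for 38% of genes in the pooled fit and 68% within sets.

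Alternatives that were run include other offsets and filters, quantile normalization, median centring, other probe set rules, array weights, fits without the line term, each numbered control alone, and each line left out. For the correlation of the 2 compounds, shared controls were simulated 100 times.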

Results

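Gene expression was measured on 28 Affymetrix arrays in U266, MM.1s, KMS11 and 8226S cells, 4 human lines of multiple myeloma, before and after treatment with 2 arsenic compounds. Myeloma is a cancer of plasma cells, the antibody-secreting cells. Arsenic trioxide (ATO) is an inorganic arsenic compound, and darinaparsin (DAR) is an organic one, in which dimethylated arsenic is linked to glutathione. Each line has 1 array after 6, 24 and 48 h of ATO, 1 after 6 and 24 h of DAR, and 2 untreated arrays, numbered control 1 and control 2. ATO was given at 2 µM, and DAR at 4 µM in U266, 3 µM in MM.1s and KMS11, and 2 µM in 8226S. The untreated arrays were taken at 0 h, so time in culture is not separated from treatment in any comparison with control.

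The arrays fall into 2 sets that the labels do not name. The controls numbered 1 and the DAR arrays form set 1 (12 arrays), and the controls numbered 2 and the ATO arrays form set 2 (16 arrays). The median signal was 82.6 in set 1 and 128.5 in set 2 as means over arrays, and 20 of 20 treated arrays were closer to the control of their own line in their own set than to the other one. Among 15437 genes tested with limma, 6752 differed between control 2 and control 1 (4356 higher, 2396 lower), with a median change over all genes of 0.215. Centring each array on its median turned this into 1567 higher and 5356 lower, and quantile normalization into 2529 higher and 2333 lower with a median of 0.025. Every comparison is therefore given in the pooled fit, which uses the 8 controls together, and within array sets, where each treatment is set against the control of the same line in its own set. A change is written as a pair, the log2 change of the pooled fit and then the change within sets with its standard error. Each treated group has 4 arrays, 1 per line. The standard error rests on the residual spread of all treatments together, moderated by limma. Against control it is therefore the same at each time for a gene, and it is not the spread of the 4 lines at that treatment. The words rose and fell are used for genes called at an adjusted p under 0.05 with the same sign in both fits.

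**Figure D1:**
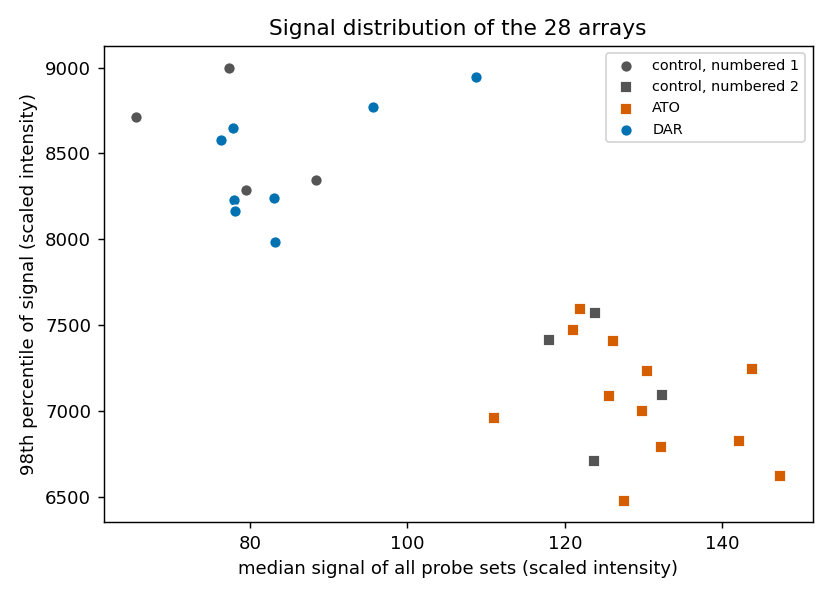
Median signal of all probe sets (horizontal axis) against the 98th percentile of signal (vertical axis), deposited units, for the 28 arrays, with treatment and array set marked. The 2 sets separate along the median, with the controls numbered 1 beside DAR and the controls numbered 2 beside ATO.

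Before treatment the 4 lines differed in the genes activated by known myeloma translocations. CCND1, which encodes cyclin D1, had a mean signal of 8611 in U266 against 331 to 491 in the other lines (adjusted p = 0.000657). MAF, a transcription factor gene, was at 15201 in MM.1s, 12460 in 8226S and 6463 in KMS11 against 409 in U266 (adjusted p = 0.00495), where the 2 controls stood at 745 and 72.6. FGFR3, a growth factor receptor gene, was at 5660 in KMS11 against 78.3 to 94.4 elsewhere (adjusted p = 0.00476), although its 2 KMS11 controls stood at 1968 and 9351. The histone methyltransferase gene NSD2 was at 7841 in KMS11 against 1266 to 2020 and did not pass (adjusted p = 0.0722). That test leaves out the control number, and NSD2 was higher in control 2 than in control 1 in each line. Among the controls numbered 1 KMS11 was at 5148 against 613 to 1186, and among those numbered 2 at 10533 against 1920 to 2855. CCND3 was lower in U266, at 410 against 1188 to 1297 (adjusted p = 0.0242), and CCND2 lay between 10400 and 17452 in the 4 lines (adjusted p = 0.456). Over all genes 2530 differed between lines in the controls, and 7978 when the control number was added to the fit.

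After 6 h of ATO the metallothionein genes, which encode small metal-binding proteins, rose in the 4 lines, as did 11 of 20 targets of the oxidative stress factor NRF2. MT2A rose by 5.83 and 5.22 ± 0.38, 37.3-fold within sets, and MT1H by 7.27 and 7.16 ± 0.50 (adjusted p within sets 3.2e-09 and 3e-09). HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose by 4.34 and 4.55 ± 0.42 (adjusted p = 2.3e-07 within sets). Of 19 heat shock genes 9 rose as well.

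Of the 8 metallothionein and metal genes tested, 7 rose and 1 did not pass after 6 h of ATO, with 7 also when adjusted over the list alone, and the list moved up by limma's camera (adjusted p = 2.49e-19). Of 20 NRF2 targets 11 rose (12 adjusted over the list alone), among them SRXN1 (1.98 and 2.10 ± 0.23), GCLM of glutathione synthesis (1.96 and 2.29 ± 0.22), the quinone reductase gene NQO1 (1.86 and 2.03 ± 0.22) and SQSTM1 (1.85 and 1.79 ± 0.19). Its camera adjusted p was 1.46e-11. Of 19 heat shock genes 9 rose (11 adjusted over the list alone), such as HSPA6 (4.29 and 3.90 ± 0.57), BAG3 (2.62 and 2.46 ± 0.23) and DNAJB1 (1.75 and 1.64 ± 0.19). Heat shock genes had camera adjusted p = 1.81e-10. Of 25 ATF4 stress response genes 8 rose (16 adjusted over the list alone), including SESN2 (2.06 and 1.69 ± 0.29) and TRIB3 (1.84 and 1.61 ± 0.24). For that list camera gave adjusted p = 1.44e-08, and adjusted p = 0.169 with an estimated correlation. In the ubiquitin and autophagy list 6 of 13 rose (7 adjusted over the list alone), including GABARAPL1 (1.77 and 1.74 ± 0.34) and VCP (0.85 and 0.58 ± 0.10). The list as a whole had camera adjusted p = 0.00359, and adjusted p = 0.0934 with an estimated correlation. The metallothionein, NRF2 and heat shock calls hold with an estimated correlation between genes (adjusted p = 0.00359, 0.0304 and 0.0284). Within sets the ATF4 and the ubiquitin and autophagy calls hold with it too (adjusted p = 0.0367 and 0.0145).

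Falls after 6 h of ATO were smaller. Of 16 cholesterol synthesis genes 4 fell and 12 did not pass (8 fell adjusted over the list alone), among them IDI1 (-1.44 and -1.30 ± 0.21) and INSIG1 (-1.46 and -1.86 ± 0.29). Camera put the cholesterol list at adjusted p = 1.59e-05, and adjusted p = 0.198 with an estimated correlation, while within sets the call holds with it (adjusted p = 0.0367). The list mean was -0.418 in the pooled fit and -0.841 within sets, and the list was higher in control 2 than in control 1 by 0.846 ± 0.293 SD, so the size of this fall depends on the control. Of 16 plasma cell genes 4 fell (4 adjusted over the list alone), including TNFRSF17, the receptor BCMA (-1.15 and -0.69 ± 0.19). Camera put the plasma cell list at adjusted p = 6.27e-05, and adjusted p = 0.0904 with an estimated correlation. MYC itself fell (-1.50 and -1.31 ± 0.36), and of the 15 genes of its ribosome biogenesis list 2 fell (2 adjusted over the list alone), with camera adjusted p = 7.06e-07 and adjusted p = 0.167 with an estimated correlation. The G1/S and G2/M lists moved down with 1 call each (1 and 1 adjusted over the list alone), with camera adjusted p = 0.00139 and 1.78e-05 and adjusted p = 0.466 with an estimated correlation for both. Within sets the G1/S call is lost (camera adjusted p = 0.162) and the G2/M call stays (0.00933). The proteasome list, 28 genes, did not move in the pooled fit (adjusted p = 0.72) but moved up within sets (adjusted p = 4.48e-22 and, with an estimated correlation, 0.0367). There were 2 proteasome genes that rose (2 adjusted over the list alone) and a line mean of 0.43 ± 0.25 SD. The list was lower in control 2 than in control 1, by -0.655 ± 0.0377 SD, so this move up depends on the control. In the pooled fit the calls of INSIG1 and TNFRSF17 were lost without MM.1s, and that of MYC without KMS11. For single genes, here and below, leaving out a line was run in the pooled fit only.

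In all, 1253 genes changed in the pooled fit after 6 h of ATO (640 higher, 613 lower), 990 within sets (583 higher, 407 lower), and 325 rose and 240 fell in both. Leaving out U266, MM.1s, KMS11 or 8226S gave 755, 305, 162 or 664 in the pooled fit, and within sets MM.1s or KMS11 gave 372 or 255. The median change over all genes was 0.142 in the pooled fit, 0.029 after quantile normalization and -0.151 after median centring, which called 185 higher and 913 lower, so the balance of directions over all genes is not settled by these data.

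After 24 h of ATO most of the metallothionein and metal genes and most of the NRF2 targets tested rose against control. Of 16 genes each of plasma cell identity and cholesterol synthesis 8 fell, and of 18 chaperones of the endoplasmic reticulum (ER) 6 fell. MT2A was up by 5.28 and 4.67 ± 0.38 and HMOX1 by 4.30 and 4.51 ± 0.42 (adjusted p within sets 5.1e-08 and 3.5e-07). TNFRSF17 was at -2.10 and -1.64 ± 0.19 (adjusted p = 1e-05 within sets), and INSIG1, which holds back sterol synthesis, was at -2.00 and -2.40 ± 0.29.

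At 24 h of ATO 7 of 8 metallothionein and metal genes rose (7 adjusted over the list alone, camera adjusted p = 7.81e-16). Of the NRF2 list, 12 of 20 targets rose (13 adjusted over the list alone, camera adjusted p = 4.04e-11), with NQO1 at 2.26 and 2.43 ± 0.22 and the malic enzyme gene ME1 at 1.35 and 1.58 ± 0.20. Of 16 plasma cell genes 8 fell and 8 did not pass (10 fell adjusted over the list alone, camera adjusted p = 3.3e-12), including MZB1, an ER protein of antibody-secreting cells (-2.36 and -2.20 ± 0.36), FKBP11 (-2.06 and -1.57 ± 0.24) and the coactivator gene POU2AF1 (-1.19 and -1.03 ± 0.18). In the cholesterol synthesis list 8 of 16 fell (11 adjusted over the list alone, camera adjusted p = 2.48e-12), such as IDI1 (-1.57 and -1.44 ± 0.21) and FDPS (-1.40 and -1.25 ± 0.19), with a list mean of -0.869 in the pooled fit and -1.29 within sets. Of 18 ER chaperones 6 fell (9 adjusted over the list alone, camera adjusted p = 1.36e-10), among them SDF2L1 (-1.56 and -1.37 ± 0.21), HSP90B1 (-1.34 and -1.08 ± 0.17) and HSPA5 (-0.94 and -0.78 ± 0.15). These 5 camera calls hold with an estimated correlation (adjusted p = 0.005 to 0.0295).

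Other lists also moved at 24 h of ATO, and none of their camera calls in the pooled fit holds with an estimated correlation. Of 25 ATF4 genes 5 rose (9 adjusted over the list alone), with SESN2 at 1.71 and 1.35 ± 0.29, camera adjusted p = 0.000278 and adjusted p = 0.358 with an estimated correlation. In the ubiquitin and autophagy list 5 of 13 rose (6 adjusted over the list alone), with camera adjusted p = 0.0306 and adjusted p = 0.172 with an estimated correlation, and within sets that call holds (adjusted p = 0.0269). Of 18 glycolysis and hypoxia genes 1 fell (5 adjusted over the list alone), with camera adjusted p = 0.00189 and adjusted p = 0.273 with an estimated correlation, and within sets the call holds (adjusted p = 0.0338). Its mean was -0.318 in the pooled fit and -0.736 within sets, with the list higher in control 2 than in control 1 by 0.835 ± 0.452 SD, so the size of this fall depends on the control too. Of 24 G1/S genes 1 fell, the helicase gene MCM7 (-1.20 and -1.19 ± 0.15, also the 1 adjusted over the list alone), with camera adjusted p = 5.49e-09 and adjusted p = 0.172 with an estimated correlation. Of 19 heat shock genes 1 was still up in both fits, BAG3 at 1.16 and 1.00 ± 0.23 (3 adjusted over the list alone). Camera did not call that list in the pooled fit (adjusted p = 0.283) and moved it up within sets (adjusted p = 1.97e-05, and adjusted p = 0.0734 with an estimated correlation), and without U266 or KMS11 the BAG3 call was lost. Of the 28 proteasome genes, limma called 0 in both fits (also 0 adjusted over the list alone), and the list leaned down in the pooled fit (camera adjusted p = 0.0517) and up within sets (2.12e-10 and, with an estimated correlation, 0.124). The direction of this list depends on the control.

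In all, 1144 genes changed in the pooled fit after 24 h of ATO (631 higher, 513 lower), 772 within sets (422 higher, 350 lower), and 220 rose and 225 fell in both. Without U266, MM.1s or KMS11 limma called 274, 152 or 126 in the pooled fit and 306, 205 or 205 within sets. The median over all genes was 0.160 in the pooled fit, 0.049 after quantile normalization and -0.138 after median centring, which called 143 higher and 768 lower.

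After 48 h of ATO 17 of 24 G1/S genes of DNA replication and 7 of 16 plasma cell genes fell. Most of the metallothionein and metal genes and most of the NRF2 targets tested rose against control. The replication genes MCM7 (-1.44 and -1.42 ± 0.15), CDC45 (-2.00 and -1.57 ± 0.26) and GINS2 (-1.81 and -1.51 ± 0.24) fell in the 4 lines. BMF, which encodes a cell-death-promoting member of the BCL2 family, rose by 1.51 and 0.99 ± 0.28 (adjusted p = 0.023 within sets). MT2A stood at 5.17 and 4.55 ± 0.38, HMOX1 at 4.33 and 4.54 ± 0.42 and NQO1 at 2.38 and 2.55 ± 0.22.

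Of 24 G1/S genes 17 fell and 7 did not pass at 48 h of ATO (22 fell adjusted over the list alone, camera adjusted p = 2.03e-22), with a line mean within sets of -0.92 ± 0.63 SD. In the G2/M list 10 of 25 fell (13 adjusted over the list alone), including BIRC5, which encodes survivin (-1.41 and -1.14 ± 0.23), and BUB1 (-0.96 and -0.85 ± 0.17), with camera adjusted p = 7.74e-14 and adjusted p = 0.142 with an estimated correlation. That list fell in U266 (-0.80) and MM.1s (-1.89) and was near 0 in KMS11 (0.11) and 8226S (-0.02). Of 16 plasma cell genes 7 fell (11 adjusted over the list alone, camera adjusted p = 8.66e-10), with TNFRSF17 at -2.16 and -1.70 ± 0.19, MZB1 at -2.24 and -2.07 ± 0.36 and FKBP11 at -2.24 and -1.75 ± 0.24. The cholesterol synthesis list had 9 of 16 that fell (11 adjusted over the list alone), with FDPS at -1.23 and -1.08 ± 0.19, camera adjusted p = 9.34e-08 and adjusted p = 0.119 with an estimated correlation. The G1/S and plasma cell calls hold with an estimated correlation (adjusted p = 0.0354 and 0.0187), and within sets so does the cholesterol call (adjusted p = 0.0294), where the list mean was -1.07 against -0.644 in the pooled fit.

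Among the lists that moved up at 48 h of ATO, 7 of 8 metallothionein and metal genes rose (7 adjusted over the list alone, camera adjusted p = 9.77e-12 and 0.0231 with an estimated correlation). So did 13 of 20 NRF2 targets (14 adjusted over the list alone, camera adjusted p = 1.64e-10 and 0.036 with an estimated correlation). Of 25 ATF4 genes 11 rose (15 adjusted over the list alone), among them TRIB3 (2.03 and 1.80 ± 0.24), SESN2 (2.01 and 1.64 ± 0.29) and the cysteine synthesis gene CTH (1.72 and 1.84 ± 0.29). ATF4 genes had camera adjusted p = 3.99e-07 and adjusted p = 0.187 with an estimated correlation. In the ubiquitin and autophagy list 5 of 13 rose (7 adjusted over the list alone), with GABARAPL1 at 1.72 and 1.69 ± 0.34, camera adjusted p = 0.00835 and adjusted p = 0.119 with an estimated correlation, and within sets the call holds (adjusted p = 0.0294). ER chaperones were mixed, with 4 of 18 that fell and 1 that rose (5 and 1 adjusted over the list alone), camera adjusted p = 0.000874 and adjusted p = 0.193 with an estimated correlation. In the 9-gene list of cell-death-promoting BCL2 members BMF was the 1 call (camera adjusted p = 0.862). In the 4-gene list of the opposite kind BCL2 rose by 0.47 and 0.63 ± 0.12 (camera adjusted p = 0.762), a call lost when any 1 line was left out. The proteasome list moved down in the pooled fit (camera adjusted p = 0.037 and adjusted p = 0.782 with an estimated correlation) and up within sets (5.55e-07 and, with an estimated correlation, 0.237). Its direction depends on the control here too.

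In all, 2573 genes changed in the pooled fit after 48 h of ATO (1443 higher, 1130 lower), 1812 within sets (981 higher, 831 lower), and 584 rose and 598 fell in both. When U266, MM.1s or KMS11 was left out the count was 1368, 827 or 738 in the pooled fit and 1129, 763 or 648 within sets. The median over all genes was 0.198 in the pooled fit, 0.070 after quantile normalization and -0.148 after median centring, which called 365 higher and 2064 lower. The ACTB log2 ratio of 3' to 5' signal, a sign of RNA quality, was higher than in control 2 in 4 of 4 lines, by 0.0768 ± 0.0613 SD (GAPDH -0.0230 ± 0.0470 SD).

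After 6 h of DAR 17 of 19 heat shock genes rose, and of 8 metallothionein and metal genes 0 rose (0 adjusted over the list alone, camera adjusted p = 0.469 in the pooled fit and 0.564 within sets). HSPA6, an inducible heat shock protein gene, rose by 5.89 and 6.29 ± 0.57, 78.1-fold within sets (adjusted p = 2.4e-07). The transcription factor gene JUN rose by 2.53 and 2.84 ± 0.31 and ATF3 by 2.58 and 3.18 ± 0.44. HMOX1 rose by 3.13 and 2.92 ± 0.42 (adjusted p = 5.3e-05 within sets), while MT2A was at -0.35 and 0.27 ± 0.38 (adjusted p = 0.601 and 0.725). IRF4, a transcription factor gene that myeloma cells depend on, fell (-1.45 and -1.08 ± 0.16).

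Of 19 heat shock genes 17 rose and 2 did not pass at 6 h of DAR (17 adjusted over the list alone, camera adjusted p = 3.54e-29 and 0.000209 with an estimated correlation), including HSPB1 (2.93 and 3.12 ± 0.37), BAG3 (2.72 and 2.88 ± 0.23), HSPA4L (1.83 and 1.89 ± 0.19) and HSPH1 (1.62 and 1.55 ± 0.14). Outside the list, the collagen chaperone gene SERPINH1 (3.56 and 3.88 ± 0.42), the prolyl hydroxylase gene P4HA2 (3.29 and 3.65 ± 0.27) and GBP1 (3.68 and 3.49 ± 0.51) were among the largest rises. Of 14 immediate early genes 5 rose (7 adjusted over the list alone), with MAFF at 2.44 and 2.39 ± 0.33 and KLF6 at 1.84 and 2.10 ± 0.29, camera adjusted p = 8.61e-07 and adjusted p = 0.141 with an estimated correlation. In the NF-kB list 6 of 16 rose (7 adjusted over the list alone), with the inhibitor gene NFKBIA at 1.26 and 1.22 ± 0.19, camera adjusted p = 0.000449 and adjusted p = 0.141 with an estimated correlation. Of 25 ATF4 genes 10 rose (14 adjusted over the list alone), with CTH at 1.75 and 1.62 ± 0.29 and CEBPG at 1.60 and 1.31 ± 0.15, camera adjusted p = 5.62e-09 and adjusted p = 0.141 with an estimated correlation. NRF2 targets had 5 of 20 that rose (7 adjusted over the list alone), with the cystine transporter gene SLC7A11 at 2.21 and 1.82 ± 0.34 and GCLM at 1.52 and 1.19 ± 0.22, camera adjusted p = 1.76e-06 and adjusted p = 0.141 with an estimated correlation. Within sets the immediate early and NF-kB camera calls hold with an estimated correlation (adjusted p = 0.0131 and 0.00494). The means of these 2 lists were 1.01 and 0.569 in the pooled fit and 1.53 and 0.904 within sets.

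Smaller groups also moved at 6 h of DAR. Of 16 p53 targets 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0888), with GADD45A at 2.18 and 2.22 ± 0.28 and the cell cycle inhibitor gene CDKN1A at 1.62 and 2.32 ± 0.38. The CDKN1A call was lost without MM.1s or KMS11. PMAIP1, which encodes the death-promoting protein NOXA, rose by 1.86 and 1.58 ± 0.31 and was the 1 call of its list (1 adjusted over the list alone, camera adjusted p = 0.0302 and adjusted p = 0.141 with an estimated correlation, and 0.125 by camera within sets). In the ubiquitin and autophagy list 4 of 13 rose (5 adjusted over the list alone), with SQSTM1 at 1.52 and 1.58 ± 0.19, camera adjusted p = 0.000488 and adjusted p = 0.0783 with an estimated correlation. Of 15 MYC and ribosome biogenesis genes 5 fell (5 adjusted over the list alone, where 1 also rose), including NOP2 (-0.99 and -1.14 ± 0.21) and CAD (-0.87 and -0.83 ± 0.17). The MYC list had camera adjusted p = 0.00962 and adjusted p = 0.507 with an estimated correlation. The plasma cell list did not move as a whole (2 fell and 1 rose, also 2 and 1 adjusted over the list alone, camera adjusted p = 0.766): IRF4 and PRDM1 (-0.82 and -0.63 ± 0.13) fell and the surface receptor gene SLAMF7 rose (1.98 and 1.73 ± 0.26). The kinase gene PIM2 (-2.17 and -1.44 ± 0.24) and the hexokinase gene HK2 (-1.92 and -1.17 ± 0.36) fell.

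In all, 2205 genes changed in the pooled fit after 6 h of DAR (1114 higher, 1091 lower), 2036 within sets (1057 higher, 979 lower), and 688 rose and 511 fell in both. The count without U266, MM.1s, KMS11 or 8226S was 1338, 826, 1019 or 1098 in the pooled fit, and within sets MM.1s or KMS11 gave 1118 or 1094. The median over all genes was -0.0998 in the pooled fit and 0.0709 after median centring, which called 1044 higher and 428 lower. The ACTB log2 ratio of 3' to 5' signal was lower than in control 1 in 4 of 4 lines, by -0.273 ± 0.154 SD (GAPDH -0.0268 ± 0.0418 SD), so RNA quality is not separated from treatment here.

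**Figure D2:**
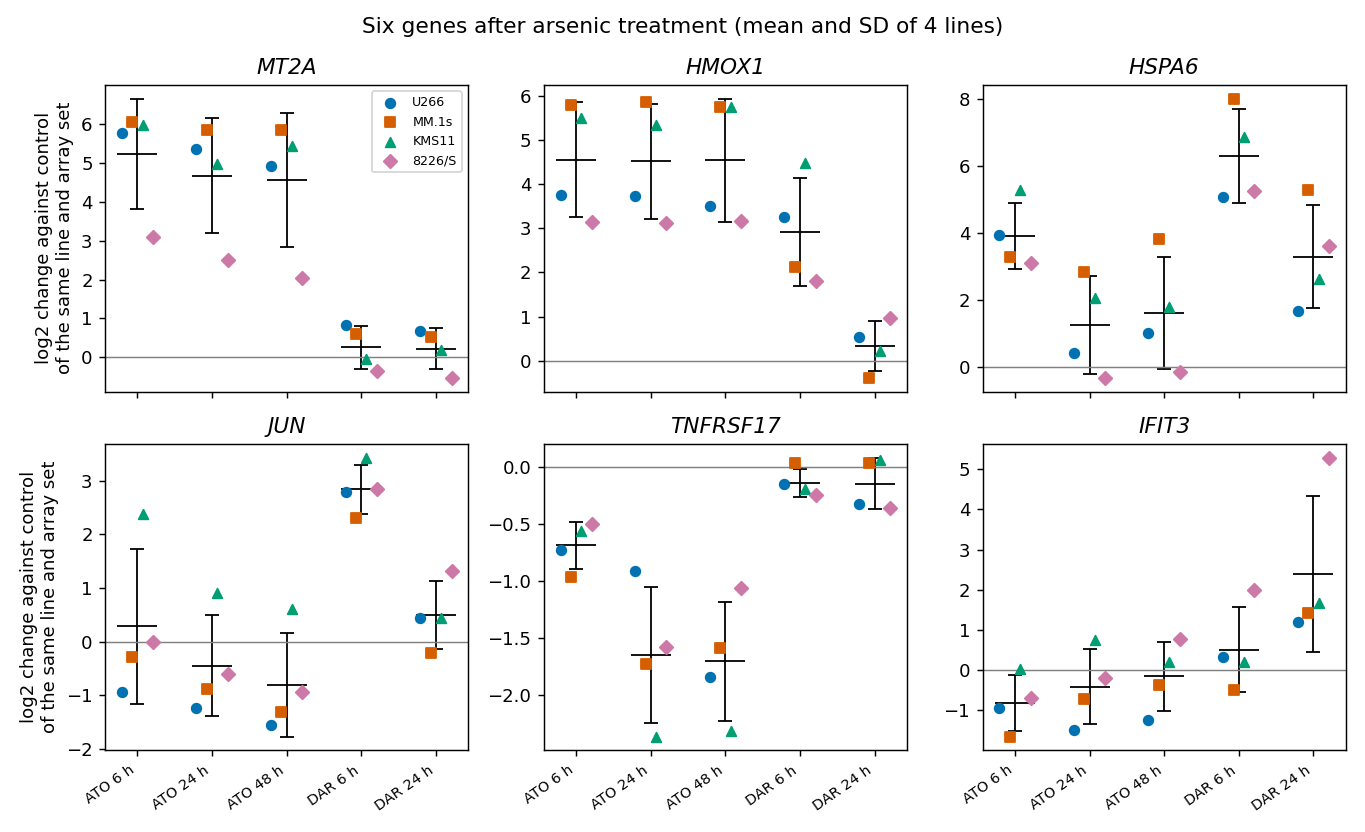
Log2 change against the control of the same line and array set (vertical axis) for MT2A, HMOX1, HSPA6, JUN, TNFRSF17 and IFIT3 after each treatment (horizontal axis), with 1 point per cell line and the mean and standard deviation of the 4 lines. MT2A rises with ATO and not with DAR, and IFIT3 after 24 h of DAR is far higher in 8226S than in the other lines.

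After 24 h of DAR few genes passed. HSPA6 was still up by 2.89 and 3.28 ± 0.57 (adjusted p = 0.01 within sets), and HMOX1 was at 0.55 and 0.34 ± 0.42 (adjusted p = 0.473 and 0.772). CLU, which encodes the chaperone clusterin, rose by 1.94 and 2.07 ± 0.27 (adjusted p = 0.0014 within sets). The interferon-induced genes IFIT3 (2.12 and 2.39 ± 0.44) and LAMP3 (2.20 and 2.46 ± 0.40) rose, as did the chemokine gene CCL5 (1.98 and 2.38 ± 0.44). The spread of IFIT3 between the lines was wider than its standard error shows, at 1.94 SD.

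Of 18 interferon response genes IFIT3 was the 1 that rose at 24 h of DAR (9 adjusted over the list alone), with camera adjusted p = 2.53e-07 and adjusted p = 0.442 with an estimated correlation. The line values of that list were 2.71 in 8226S, 0.90 in U266, 0.62 in KMS11 and 0.18 in MM.1s. Of 19 heat shock genes HSPA6 was the 1 that rose (1 adjusted over the list alone), with camera adjusted p = 0.00738 and adjusted p = 0.442 with an estimated correlation. The G2/M list, 25 genes, moved up by 0.40 ± 0.19 SD in the lines with camera adjusted p = 5.82e-09 and adjusted p = 0.442 with an estimated correlation, but limma called 0 of its genes in both fits, also 0 adjusted over the list alone. The list of markers of other cell types, 13 genes, moved down with camera adjusted p = 0.0185 and adjusted p = 0.442 with an estimated correlation. Within sets camera called the interferon and G2/M lists (adjusted p = 5.09e-12 and 7.4e-07) and not the heat shock list or the markers of other cell types (0.61 and 0.277). None of these calls at 24 h of DAR holds with an estimated correlation in either fit.

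In all, 492 genes changed in the pooled fit after 24 h of DAR (246 higher, 246 lower), 96 within sets (76 higher, 20 lower), and 43 rose and 10 fell in both. Leaving out U266, MM.1s, KMS11 or 8226S gave 102, 64, 1 or 0 by limma in the pooled fit and 87, 62, 1 or 0 within sets. Without 8226S no call was left, so those of HSPA6, IFIT3, LAMP3, CCL5 and CLU were lost with all others. Without KMS11 most of these were lost too, as 1 gene was called. The median over all genes was -0.0790 in the pooled fit and 0.0872 after median centring, which called 130 higher and 85 lower. The ACTB ratio was higher than in control 1 in 3 of 4 lines, by 0.212 ± 0.199 SD.

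DAR and ATO were run in different array sets, so their direct comparison carries the set difference, and the values within sets, DAR against its control minus ATO against its control, are given first. After 6 h the metallothionein genes were lower with DAR than with ATO, MT2A by -4.96 ± 0.53 (adjusted p = 1.4e-05) and MT1H by -7.16 ± 0.71 (adjusted p = 4.7e-06). JUN was higher with DAR by 2.55 ± 0.44 (adjusted p = 0.0025), KLF6 by 2.14 ± 0.41, the NF-kB feedback gene TNFAIP3 by 1.29 ± 0.21 and SLAMF7 by 1.80 ± 0.37. HMOX1 did not pass at 6 h (-1.63, 95% interval -2.85 to -0.42, adjusted p = 0.156) and was lower with DAR at 24 h by -4.18 ± 0.59 (adjusted p = 0.00073). TNFRSF17 was 2.83-fold higher with DAR at 24 h (adjusted p = 0.012).

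By list, 7 of 8 metallothionein and metal genes were lower with DAR at 6 h in both fits (7 adjusted over the list alone), with a difference of -4.03 ± 0.88 SD in the lines and camera adjusted p = 7.23e-20 within sets, 0.00219 with an estimated correlation. At 24 h 5 were lower (7 adjusted over the list alone), with -3.42 ± 0.93 SD and 2.74e-21, 0.00154 with an estimated correlation. Of 14 immediate early genes 3 were higher with DAR at 6 h (3 adjusted over the list alone, 1.61 ± 0.85 SD, camera adjusted p = 7.2e-10 within sets and 0.0312 with an estimated correlation). Of 16 NF-kB genes 2 were higher (5 adjusted over the list alone, 0.93 ± 0.33 SD, 8.56e-08 and 0.00525). Of 20 NRF2 targets 2 were lower at 6 h (3 adjusted over the list alone, -0.76 ± 0.30 SD), with camera adjusted p = 3.71e-09 within sets and adjusted p = 0.0507 with an estimated correlation. At 24 h 3 of them were lower (11 adjusted over the list alone, -1.02 ± 0.46 SD, 1.52e-17 and 0.00752), including NQO1 (-1.62 ± 0.31). The heat shock list was higher with DAR at 6 h by 0.42 ± 0.20 SD, with camera adjusted p = 0.00334 within sets and adjusted p = 0.297 with an estimated correlation. Of 16 plasma cell genes 1 was higher with DAR at 24 h (6 adjusted over the list alone, 0.63 ± 0.19 SD, camera adjusted p = 1.89e-08 within sets and 0.0397 with an estimated correlation). The cholesterol synthesis list was also higher by 1.05 ± 0.66 SD (4.58e-17 and 0.0365, 5 genes adjusted over the list alone).

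In the direct comparison of the arrays, without the controls, several of these list differences were smaller. The immediate early list differed by 0.572 and the NF-kB list by 0.257 at 6 h (camera adjusted p = 0.0808 for both), and the cholesterol list by 0.20 at 24 h (camera adjusted p = 0.0105 and adjusted p = 0.502 with an estimated correlation). These 3 lists were higher in control 2 than in control 1 by 1.03 ± 0.446 SD, 0.670 ± 0.139 SD and 0.846 ± 0.293 SD. In number, most of each difference within sets is this shift between the controls. If the shift is one of array processing it masks the direct values, and this is not settled here. The metallothionein list differed by -5.16 at 6 h (camera adjusted p = 1.63e-11 and 0.0422 with an estimated correlation) and by -4.55 at 24 h (8.32e-10, and adjusted p = 0.0798 with an estimated correlation). For NRF2 targets it was -0.570 at 6 h (camera adjusted p = 0.12) and -0.829 at 24 h (0.00721, and adjusted p = 0.474 with an estimated correlation). The heat shock list differed by 0.601 at 6 h (2.75e-06, and adjusted p = 0.164 with an estimated correlation) and the plasma cell list by 0.786 at 24 h (1e-05, and adjusted p = 0.0874 with an estimated correlation).

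BCL2 family genes named here did not pass in the comparison of the compounds. BCL2 differed by 0.10 (95% interval -0.24 to 0.44) at 6 h and by 0.03 (-0.32 to 0.37) at 24 h, MCL1 by 0.33 (-0.17 to 0.83) and 0.13 (-0.37 to 0.63), and PMAIP1 by 0.89 (-0.01 to 1.78) at 6 h. The ATF4 target DDIT3 differed by 0.34 (-0.51 to 1.20) at 6 h. The p53 targets GADD45A (1.11, interval 0.30 to 1.92, adjusted p = 0.144) and CDKN1A (1.82, interval 0.71 to 2.92, adjusted p = 0.072) did not pass either, although their intervals lie above 0. BAG3 differed by -0.37 (-1.04 to 0.30) at 24 h.

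In 8226S both compounds were given at 2 µM, and the values of that line against its own controls are set side by side. At 6 h MT2A was at 3.10 with ATO and -0.34 with DAR, HMOX1 at 3.15 and 1.81, HSPA6 at 3.10 and 5.25, and JUN at -0.002 and 2.84. At 24 h MT2A was at 2.51 with ATO and -0.52 with DAR, HMOX1 at 3.12 and 0.97, TNFRSF17 at -1.58 and -0.36, and IFIT3 at -0.19 and 5.28. In the other 3 lines the dose of DAR was above that of ATO, so compound and dose are not separated there.

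Within sets 341 genes differed between DAR and ATO at 6 h (154 higher with DAR, 187 lower) and 38 at 24 h (19 and 19). Without U266, MM.1s, KMS11 or 8226S there were 165, 60, 111 or 149 at 6 h, and without U266, MM.1s or KMS11 there were 10, 8 or 13 at 24 h. The direct comparison called 5042 at 6 h (1877 higher, 3165 lower) and 5452 at 24 h (1922 higher, 3530 lower), of which 1238 and 1469 had the opposite sign within sets. In it, leaving out U266, MM.1s or KMS11 gave 2884, 2471 or 3100 at 6 h, and MM.1s or KMS11 gave 2520 or 2993 at 24 h. Its median over all genes was -0.202 and -0.218, and median centring called 3662 higher and 1157 lower at 6 h and 3847 higher and 1368 lower at 24 h, with medians of 0.262 and 0.246.

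**Figure D3:**
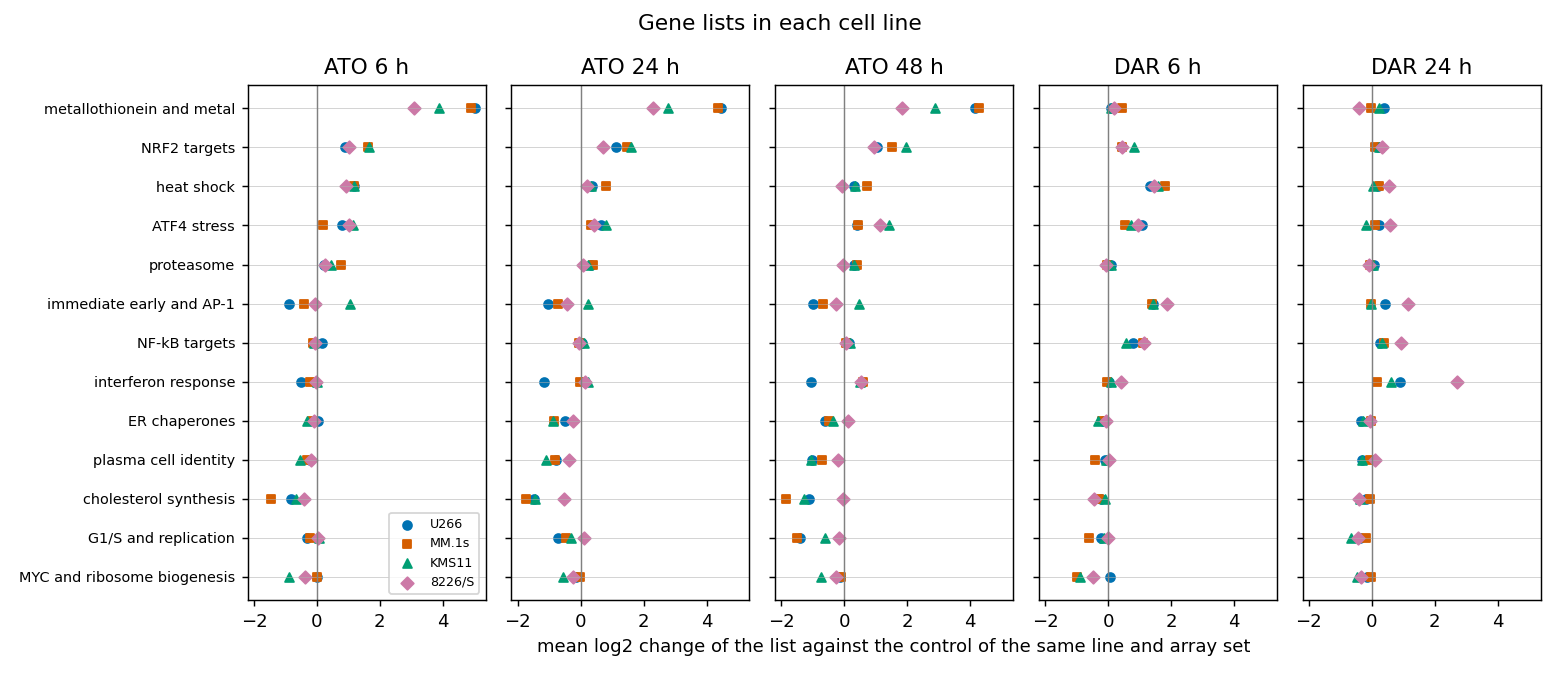
Mean log2 change of 13 gene lists against the control of the same line and array set, by treatment and cell line. The metallothionein and NRF2 lists are high with ATO at each time, the heat shock list is high at 6 h of both compounds, and the plasma cell and replication lists are low late in ATO.

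Changes of the 2 compounds over all genes were compared with each compound set against the controls of its own set, which share no arrays. The correlation was 0.323 at 6 h and 0.217 at 24 h, with a covariance of 0.0594 and 0.0296. By line it was 0.186 ± 0.104 SD at 6 h and 0.124 ± 0.0892 SD at 24 h, highest in KMS11 (0.338 and 0.255). At 6 h 221 genes were higher with both compounds where independent calls would give 39.9, and 109 were lower with both where they would give 25.8. At 24 h 19 were higher and 6 lower with both (2.08 and 0.453 for independent calls). Genes called in opposite directions numbered 8 and 7 at 6 h, and 0 at 24 h. The calls of the compounds come from the same fit, where the tests of a gene share its residual spread. Genes with little spread can be called for both without a shared response. The values for independent calls therefore do not measure what chance would give. With all 8 controls shared by the 2 compounds the correlation was -0.0695 and -0.277, against 0.333 and 0.333 in simulations of shared controls without any treatment effect, so the shared-control values carry the array sets.

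Between 6 and 24 h of DAR the heat shock response went down. Of 19 heat shock genes 14 fell (16 adjusted over the list alone, camera adjusted p = 3.91e-34 and 7.4e-05 with an estimated correlation), such as HSPA4L (-2.17 ± 0.19), BAG3 (-2.25 ± 0.23) and HSPB1 (-2.54 ± 0.37), given here within sets. JUN (-2.34 ± 0.31) and GADD45A (-1.70 ± 0.28) fell. XAF1, an interferon-induced gene, rose by 3.00 ± 0.44. Of 25 G2/M genes 5 rose (15 adjusted over the list alone, camera adjusted p = 1.78e-16 and adjusted p = 0.175 with an estimated correlation). Of 18 interferon genes 3 rose (8 adjusted over the list alone, 1.68e-08, and adjusted p = 0.175 with an estimated correlation). Of 25 ATF4 genes 3 fell (8 adjusted over the list alone), with camera adjusted p = 3.67e-10 and adjusted p = 0.175 with an estimated correlation. Immediate early genes had 5 of 14 that fell (9 adjusted over the list alone, camera adjusted p = 6.85e-11 and adjusted p = 0.126 with an estimated correlation), and within sets the call holds (adjusted p = 0.0348). In all, 287 genes differed in the pooled fit (125 higher, 162 lower) and 1184 within sets (627 higher, 557 lower), and leaving out U266, MM.1s, KMS11 or 8226S gave 167, 55, 66 or 117 in the pooled fit. Median centring called 17 higher and 83 lower. The log2 ratio of 3' to 5' signal was higher at 24 h than at 6 h of DAR in 4 of 4 lines, by 0.485 ± 0.0620 SD for ACTB and 0.104 ± 0.0188 SD for GAPDH, so RNA quality is not separated from time in this comparison.

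Between 6 and 24 h of ATO 10 genes differed in the pooled fit (3 higher, 7 lower) and 71 within sets (22 higher, 49 lower). The heat shock list moved down, with 3 of 19 that fell (12 adjusted over the list alone, camera adjusted p = 4.44e-23 and 0.000893 with an estimated correlation): HSPH1, DNAJB1 by -1.16 ± 0.19 and BAG3 by -1.47 ± 0.23, calls that were lost without U266, KMS11 or 8226S. ER chaperones (8 lower adjusted over the list alone, camera adjusted p = 1.1e-17 and 0.00392 with an estimated correlation) and plasma cell genes (4 lower adjusted over the list alone, 1.3e-07 and 0.0176, and adjusted p = 0.0691 with an estimated correlation within sets) also moved down. Leaving out U266, MM.1s, KMS11 or 8226S gave 0, 3, 0 or 5 genes by limma. Between 24 and 48 h of ATO limma called 0 genes in the pooled fit (413 at an unadjusted p under 0.05) and 0 within sets (983 at an unadjusted p under 0.05), and 1 without KMS11 in the pooled fit. There camera moved the G1/S list down (adjusted p = 5.36e-28 and 0.0469 with an estimated correlation, which is 0.116 within sets, 9 genes lower adjusted over the list alone, -0.58 ± 0.35 SD) and the G2/M list down (1.49e-30, and adjusted p = 0.0725 with an estimated correlation).

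A difference between the compounds in the change from 6 to 24 h was called by limma for 0 genes in the pooled fit (881 at an unadjusted p under 0.05) and for 77 within sets (41 higher, 36 lower). A response to arsenic that differs between the lines was called for 0 genes in the pooled fit (366 at an unadjusted p under 0.05, and 1 gene without 8226S) and for 7 within sets (1283 at an unadjusted p under 0.05).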

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

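The tests of the metallothionein and interferon patterns in this part were chosen after the results were seen. Of 239 groups of 4 lines or arrays examined, 9 had 1 value far from the other 3, and chance alone marks about 1 group in 20 this way.

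In 8226S 4 values after ATO were smaller than in the other lines. MT2A was up by 3.10 after 6 h, against 5.77 to 6.04 in the other lines, and the heat shock list by 0.936 against 1.18 to 1.19. The glutathione reductase gene GSR was up by 0.306 after 24 h of ATO against 0.928 to 0.989, and the glutathione transferase gene GSTM3 by 0.445 after 48 h against 1.29 to 1.35. With DAR 2 values of this line were above those of the others, the immediate early list at 1.88 after 6 h against 1.40 to 1.42 and IFIT3 at 5.28 after 24 h against 1.20 to 1.66. In KMS11 the NRF2 list was at 0.826 after 6 h of DAR against 0.430 to 0.454. The dose of DAR was lowest in 8226S.

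2 arrays stood apart in signal. The 8226S array after 6 h of DAR had a median signal of 108.66 against 76.3 to 78.0 in the other lines. The U266 array after 24 h of DAR had a log2 ratio of 3' to 5' signal of GAPDH of 0.208 against 0.0358 to 0.0571.

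The response to arsenic differed between lines within sets for NFKBIZ and LMNA (adjusted p = 0.0249 for each) and for CLU and GUSBP11 (0.049996 for each, just under the threshold), while the pooled fit gave 0.608 for NFKBIZ, CLU and GUSBP11 and 1.00 for LMNA. NFKBIZ, an NF-kB regulator gene, changed on average by -0.80 in U266, 0.43 in MM.1s, 1.86 in KMS11 and 1.46 in 8226S. LMNA, which encodes the nuclear lamins A and C, changed by -0.083, 0.81, 2.06 and 0.55, CLU by 1.07, 1.59, 2.82 and 1.91, and the pseudogene GUSBP11 by -0.039, -0.42, -1.47 and 0.11, each in the same order. These genes were taken from the 10 with the smallest p in the pooled fit, and the other genes called within sets are not named. As the dose of DAR differed between lines, except for MM.1s and KMS11, line and dose are not separated in this test. Between times 10 genes differed for ATO (24 against 6 h) and 287 for DAR.

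Probe sets without a single gene symbol were tested apart, 7036 of them. Called in both fits were 51, 55 and 166 after 6, 24 and 48 h of ATO, and 309 and 60 after 6 and 24 h of DAR, so the 166 and 309 are changes that the gene counts do not hold.

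Metallothionein genes rise with ATO and not with DAR. The shift between the array sets is 1.32 ± 0.402 SD over the 6 metallothionein genes (control 2 minus control 1), while the arrays of the compounds differ by 6.36 ± 0.858 SD at 6 h without any control, a gap larger than the shift by 5.04 ± 1.19 SD, so the shift does not account for it. That DAR reached the cells too weakly to give any stress response is excluded as well, but no more than that. The heat shock list was higher with DAR than with ATO at 6 h by 0.421 ± 0.201 SD, in 4 of 4 lines (0.143 in U266, 0.611 in MM.1s, 0.418 in KMS11 and 0.511 in 8226S). Heat shock genes were already seen to rise with DAR when this test was chosen. Whether DAR was too weak to raise metallothionein genes is not told by it.

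Of 18 interferon response genes 1, IFIT3, rose after 24 h of DAR, and the camera call of the list is lost with adjusted p = 0.442 with an estimated correlation. Whether 1 cell line carries the rise cannot be told: without 8226S the list mean over the other 3 lines was 0.566 ± 0.363 SD. Time in culture without a matched untreated array cannot be excluded either: the list median after 24 h of ATO was -0.183, with a line mean of -0.206 ± 0.655 SD, a spread too wide to tell a rise from a fall.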

How the results depend on the processing

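Of the values of 24 counts and correlations under the alternatives, 209 stayed within the limits set for a change, 139 moved by more (counts by over 1.5 times) and 4 changed sign. For 88 named genes and 210 of their results, 3359 alternative values were computed: 2941 kept sign and call, 418 kept the sign and lost the call, and 0 changed sign. The 210 results were chosen as called in both fits, so the fit within sets keeps them by construction. The fits without the line term, without the variance trend and with the compared groups alone leave the estimates unchanged, so no sign could change there. Many of the 210 results were also picked for the same sign in the 4 lines, which fixes the sign when a line is left out. The 0 is thus in large part built in. The runs with 1 numbered control, with swapped controls and with all probe sets separately were not made for named genes. Leaving out a line was run for named genes in the pooled fit and not within sets. Of the lost calls 137 came without the line term, 52 without KMS11, 44 with the compared groups alone, 42 without MM.1s, 32 without U266, 29 with median centring, 29 with the mean of all probe sets and 22 without 8226S, with fewer in each other setting. The alternatives within array sets, the leave-one-out runs on them and the estimates within each line were added after the data were seen. Where a cause is not named, the cause was not tested.

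Without the replicate block (no replicate block, a fit without the cell line pairing) the counts were 54, 17 and 81 for ATO at 6, 24 and 48 h, 149 and 0 for DAR at 6 and 24 h, 1520 and 1583 for DAR versus ATO, 0 and 2 for the change over time of ATO (24 versus 6 h) and DAR, and 2871 for control 2 versus control 1. Without the block, differences between lines enter the residual spread.

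With all probe sets separately, which counts a gene once per probe set, the calls were 2051, 1885 and 4259 for ATO at 6, 24 and 48 h, 4598 and 985 for DAR, 9438 and 9817 for DAR versus ATO at 6 and 24 h, 34 for agent by time, 17 and 792 for the change over time of ATO and DAR, 11974 for the controls and 4042 for the lines at baseline. With the mean of all probe sets DAR 24 h had 170 and ATO 24 versus 6 h 5, and within array sets DAR 24 h had 58 and DAR versus ATO at 24 h 25.

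With only the arrays of the groups compared the counts were 163, 104 and 295 for ATO, 606 and 1 for DAR and 489 for DAR 24 versus 6 h. With arrayWeights they were 4877 and 4556 for DAR at 6 and 24 h, 15 for agent by time, and 258 and 2 for ATO 24 versus 6 h and 48 versus 24 h. With eBayes without trend DAR 24 h had 205 and ATO 24 versus 6 h 4, and within array sets ATO 24 h had 495, DAR 24 h 38, and DAR versus ATO 161 and 21. With median centring DAR 24 h had 215, ATO 24 versus 6 h 0 and DAR 24 versus 6 h 100, and within array sets ATO had 641 at 6 h and 502 at 24 h, and DAR versus ATO 164 at 6 h. Quantile normalization within array sets gave 57 for DAR 24 h, and no filter gave 24 for DAR versus ATO at 24 h.

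A control of the other set brings the set difference into the comparison. With only the controls numbered 1 the counts were 6977, 7155 and 7855 for ATO and 1359 and 18 for DAR. With only the controls numbered 2 they were 520, 325 and 1005 for ATO and 6992 and 6944 for DAR. With only the arrays of the treatment's set ATO 24 h had 626, DAR 24 h 63, ATO 24 versus 6 h 21, ATO 48 versus 24 h 1 and DAR 24 versus 6 h 913. The set block gave 96 for DAR 24 h, 341 and 38 for DAR versus ATO, 77 for agent by time, 71 and 1184 for ATO and DAR over time and 7 for line by arsenic, and the set as an additive block gave 7978 for the lines at baseline. For DAR versus ATO, DAR less control 1, ATO less control 2 gave 150 and 14, and DAR less control 2, ATO less control 1 gave 8983 and 9175.

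Leaving out each line gave lowest and highest counts of 162 and 755 for ATO 6 h, 126 and 766 for ATO 24 h, 738 and 1985 for ATO 48 h, 826 and 1338 for DAR 6 h, 0 and 102 for DAR 24 h, 2471 and 3751 for DAR versus ATO at 6 h, and 2520 and 3753 at 24 h. Over time they were 0 and 5 for ATO 24 versus 6 h, 55 and 167 for DAR, and 0 and 1 for ATO 48 versus 24 h, and line by arsenic had 0 and 1. Within array sets they were 255 and 802 for ATO 6 h, 205 and 951 for ATO 24 h, 648 and 1976 for ATO 48 h, 1094 and 1837 for DAR 6 h, 0 and 87 for DAR 24 h, 60 and 165 for DAR versus ATO at 6 h, and 8 and 47 at 24 h. DAR 24 h rests on KMS11 and 8226S together, with 1 and 0 genes without them.

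In the 5 comparisons with control camera called 57 lists and camera with an estimated correlation 13. Camera on the set block fit called 58, and camera on the set block fit with an estimated correlation 24, which are calls of that fit and not a share of the 57. The correlation estimated in the pooled fit carries the difference between the control sets. How many calls are lost through it was not tested. The correlation of the compounds, 0.323 at 6 h and 0.217 at 24 h, changed sign with all 8 controls for both agents (-0.0695 and -0.277) and with the numbered controls swapped between the agents (-0.600 and -0.720), where the set difference enters the 2 changes with opposite signs. It was 0.110 and 0.105 within U266, 0.168 and 0.0779 within MM.1s, and 0.129 and 0.0591 within 8226S.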

Other observations

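Several tests here were chosen after the result was seen: those of array processing, those of gene lists between the controls, the splits within sets, the limit to splits that part the arrays of each line, and the 3' to 5' ratios of treated arrays against controls or each other. The tests of spikes and RNA between sets and the first form of the splits were written before.

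Some lists differed between lines without a test of that difference. After 48 h of ATO the G2/M list ran from -1.89 in MM.1s to 0.11 in KMS11. Between the controls of the 2 sets camera called several lists, and none of these calls holds with an estimated correlation. Of 28 proteasome genes 25 were lower in control 2 and 1 higher (26 and 1 adjusted over the list alone, camera adjusted p = 1.26e-16 and adjusted p = 0.362 with an estimated correlation), with a list mean of -0.655 ± 0.0377 SD over 4 lines. Of 14 immediate early genes 7 were higher (7 adjusted over the list alone, camera adjusted p = 0.0490 and adjusted p = 0.634 with an estimated correlation), and of 18 glycolysis and hypoxia genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone, 0.0490, and adjusted p = 0.606 with an estimated correlation). At the same camera p of 0.0490, 9 of 16 cholesterol synthesis genes were higher and 1 lower (10 and 1 adjusted over the list alone, list mean 0.846 ± 0.293 SD, adjusted p = 0.653 with an estimated correlation), and 7 of 13 markers of other cell types were higher (8 adjusted over the list alone, 0.920 ± 0.229 SD, adjusted p = 0.460 with an estimated correlation). Lower in control 2 were 7 of 15 MYC, 8 of 19 heat shock, 7 of 24 G1/S, 5 of 25 G2/M and 6 of 20 NRF2 genes (7, 8, 7, 3 and 6 adjusted over the list alone), and 2 G1/S and 2 NRF2 genes were higher (2 and 2 adjusted over the list alone). These 5 lists had camera adjusted p = 0.0127 to 0.0418 and adjusted p = 0.606 to 0.681 with an estimated correlation. Among genes picked after the values were seen, FOS was higher in control 2 than in control 1 by 3.18 ± 2.09 SD, EGR1 by 2.59 ± 1.28 SD, JUN by 0.607 ± 0.370 SD, the hexokinase gene HK2 by 1.51 ± 0.994 SD and PFKFB4, a regulator gene of glycolysis, by 2.61 ± 1.35 SD, over 4 lines. Among 16 genes of arsenic and glutathione handling 3 rose and 1 fell after 48 h of ATO (also 3 and 1 adjusted over the list alone, camera adjusted p = 0.145). The glycolysis and hypoxia list, 18 genes, moved down after 48 h of ATO with 2 genes that fell (3 adjusted over the list alone), camera adjusted p = 0.0307 and adjusted p = 0.449 with an estimated correlation. Of the 6 translocation markers tested CCND1 fell there, a call lost without U266 (1 adjusted over the list alone, camera adjusted p = 0.0106 and adjusted p = 0.123 with an estimated correlation).

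The controls numbered 2 differ from the controls numbered 1 in many genes. That array processing differed between the sets fits the values: across genes the shift between controls correlated at 0.829 with the shift between ATO and DAR arrays. That spiked control transcripts were hybridised differently fits too, with the 4 spikes lower in set 2 by -0.756 on the log2 scale, though the spikes also carry the scaling of each array. That RNA was more degraded in one set cannot be told from the ACTB ratio of 3' to 5' signal, which was lower by -0.541 in set 2 (0.718 ± 0.253 SD in set 1 and 0.177 ± 0.081 SD in set 2), while that of GAPDH was 0.027 and -0.146. A difference in array processing and one in the cells before lysis cannot be separated here.

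Other splits of the same arrays were tested for each count. For ATO at 6, 24 and 48 h, 6, 6 and 3 of 81 splits within lines called as many genes as the real 1253, 1144 and 2573, and for DAR at 6 and 24 h 3 and 9 of 81 called as many as 2205 and 492. The highest other splits called 7743, 7852, 7982, 7401 and 7738, and these take a control of the other set as the treated array, so they follow the array set and point to the structure of the samples. Because these splits exchange controls of different sets, their shares are not read as showing whether chance is excluded. Splits added after the result was seen exchange the treated array with the control of its own line and set, 8 for each comparison, too few for a share under 0.05. There the real split called 990, 772, 1812, 2036 and 96 genes and the highest other split 2, 6, 407, 47 and 1.

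For the comparisons of 4 arrays with 4 the lines pair the arrays, and 8 splits part the 2 arrays of each line, too few for a share under 0.05. The real split called 5042 genes for DAR versus ATO at 6 h (1 of 8 splits as large, highest other 1) and 5452 at 24 h (1 of 8, highest other 0). These follow the array set, and within sets the counts were 341 and 38. For control 2 versus control 1, a split that is the array set, it called 6752 (1 of 8, highest other 0). For DAR 24 versus 6 h it called 287 (1 of 8, highest other 0), for ATO 24 versus 6 h 10 (1 of 8, highest other 0), and for ATO 48 versus 24 h 0 (8 of 8, highest other 0). The other 27 splits of each comparison keep the 2 arrays of at least 1 line together, so that the line differences weigh on them, and called at most 8. For agent by time the real count was 0, so 100 of 100 splits reach it by construction and nothing on chance follows (highest other 2923, from splits that mix compounds and sets, a structure of the samples). The same holds for ATO 48 versus 24 h, and the 77 genes of agent by time within sets were not tested by splits.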
